A study of Mus musculus with 6 samples.

How the data were processed

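The series measured gene expression by RNA sequencing in mouse lung Th17 cells. Per the labels' protocols, male and female reporter mice of 4 to 6 weeks of age were exposed to 150 µg of Saccharopolyspora rectivirgula, a bacterium that serves as the antigen in a model of hypersensitivity pneumonitis. The mice carried a green reporter of IL-17A and a red reporter of Foxp3. Lung cells positive for CD44, TCRβ, CD4 and the IL-17A reporter and negative for the Foxp3 reporter were sorted, so Il17a and Foxp3 were themselves used to choose the cells. Directional libraries were made from polyadenylated RNA, with 20 ng of total RNA as input. The 6 libraries fell into 3 labelled WT and 3 labelled Itk-/-, where Itk is a Tec family kinase that acts downstream of the T cell receptor (TCR).

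The deposited table gives FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) per gene symbol and library. Per the submitters' processing notes, the tools used were cutadapt 1.8, TopHat2 2.0.13 and Cuffnorm 2.2.1, with the genome build mm10. The gene annotation and the library scaling used in Cuffnorm are not given in the sources used here. The table holds 23361 rows, of which 6317 were at 0 in all 6 libraries. A spreadsheet had turned 27 symbols into dates, and these rows were never named. Positions on GRCm38 (mm10) came from GENCODE vM21 or, through older symbols, from RefSeq names, and 23160 rows were matched.

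Total counts are not part of the table, but the low values carry a step. Over 2669 genes with 1 annotated transcript, between 64.4% and 69.5% of values under 5 fragments lay within 0.2 of a whole number of fragments, against 40% by chance. In units of 1e+06 fragments on the file's own scale, the step gave 16.54, 14.26 and 18.14 for WT replicates 1 to 3 and 15.2, 14.4 and 12.48 for Itk-/- replicates 1 to 3. These are estimates after Cuffnorm's scaling, and the deepest exceeded the shallowest by a factor of 1.45. The variance between replicates was above that of counting alone even for genes with 5 to 20 fragments. The mean factor there was 3.6 in the WT group and 3.44 in the Itk-/- group. For genes with 100 to 1000 fragments it was 4.56 and 3.75. No 2 libraries were therefore treated as copies, but this excess cannot show whether the libraries came from separate animals.

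FPKM values are not counts, so no count test was run. Genes with a mean FPKM of at least 1 over the 6 libraries were tested on log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, using lmFit and eBayes with an intensity trend and genotype as the only term. Tests were two-sided, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are Itk-/- over WT on the log2(FPKM + 1) scale, which understates the change of low genes, while ratios are of mean FPKM. All adjusted p-values come from this limma fit or from limma's list tests. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these samples, which may be technical. On data simulated from these libraries over 10997 genes, the fit recovered 68% of genes changed by 0.5 log2 and 96% of those changed by 1 log2, with 6 false calls. Each gene was drawn independently with normal noise from the fit's own variances, and 100 genes were changed at each size. The figures thus cannot show how the fit does with correlated genes, outlying values or more widespread change.

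Gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01 where at least 5 members were measured, with Itk left out. The T cell lists were the Th17 programme, pathogenic and non-pathogenic Th17 signatures, Th1 and Th2 programmes, regulatory, follicular helper and innate-like T cell markers, proximal TCR signalling, TCR-induced immediate response genes, inhibitory receptors, memory and lymphoid homing, lung homing and tissue residency, and the IL-2, IL-7 and STAT5 response. The general lists were the interferon response, cell cycle, glycolysis and hypoxia response, oxidative phosphorylation, cholesterol synthesis, heat shock and dissociation stress, apoptosis regulators and mitochondrially encoded transcripts. Lists of other cells covered macrophages and dendritic cells, neutrophils, B and plasma cells, lung epithelium, endothelium and fibroblasts, CD8 T and NK cells, mast cells with basophils and eosinophils, and erythroid cells. Sex-linked transcripts and neighbours of Itk on chromosome 11 completed the 32 lists, of which 29 could be tested. A simulated shift of the cell cycle list by 0.3 log2 was called, with 0 other calls. The genes were simulated independently of each other, so this cannot show how often correlated lists are called falsely.

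The genes named in the text were chosen by a rule fixed in advance. It took Itk, the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, passing over predicted genes, microRNA and snoRNA names. It also took up to 4 called members of each list with the smallest p, and a fixed set of T cell cytokines, receptors, transcription factors and kinases. Of the genes this rule chose, 1 is not reported here. Any other gene named below was chosen after its values were seen.

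The alternatives were a pseudocount of 0.1 or 5, no filter on level, a minimum mean FPKM of 5, median-ratio, TPM and quantile scaling, library weights, eBayes without the trend or in its robust form, the replicate number as a block, each library left out in turn, camera with an estimated correlation, and fry. A fit without microRNA, snoRNA and scaRNA rows and a minimum fold of 1.5 were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15, with pandas 2.3.3 and numpy 2.4.6.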

Results

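Gene expression was measured in Th17 cells, the IL-17-producing helper T cells, sorted from the lungs of mice exposed to a bacterial antigen that causes hypersensitivity pneumonitis. The series compared 3 libraries labelled WT with 3 labelled Itk-/-. Summed FPKM lay between 551890 and 570120 in the WT libraries and between 534583 and 546017 in the Itk-/- libraries. Values below are mean FPKM ± SD with n = 3 libraries per group, and positions are on GRCm38. The study's title names the question as the part that the kinase Itk plays in Th17 responses during this lung disease.

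Itk mRNA was not lower in the libraries labelled Itk-/-. Itk (chromosome 11, 46325150 to 46389515, minus strand) was at 69.5, 72.5 and 69.1 FPKM in WT replicates 1 to 3. It was at 93.9, 94.0 and 93.1 FPKM in Itk-/- replicates 1 to 3. The difference was 0.41 log2 (95% interval 0.32 to 0.50, limma adjusted p = 3.89e-04), higher in 3 of 3 libraries. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 allows. The labels do not state which part of the gene was disrupted, and a gene-level FPKM cannot separate a transcript of a disrupted allele from an intact one. The level therefore leaves the labels unchecked, and every direction below is that of the libraries labelled Itk-/- over those labelled WT. Of the related kinases, Txk was lower (13.4 ± 1.16 against 8.47 ± 0.932 FPKM, adjusted p = 0.00435), while Tec stood at 34.6 ± 1.16 and 33.6 ± 0.213 FPKM (adjusted p = 0.604).

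The cytokine genes moved in different directions. Il10, which encodes an anti-inflammatory cytokine, was 3.18-fold lower in the libraries labelled Itk-/-, at 184 ± 1.37 FPKM in WT and 57.9 ± 1.20 in Itk-/-. Ifng, the signature cytokine of Th1 cells, was 1.74-fold higher, at 114 ± 5.79 against 198 ± 9.02 FPKM. Il17a was 1.35-fold lower (572 ± 11.6 against 423 ± 4.32 FPKM), in cells that were chosen by an IL-17A reporter. Il17f was 1.22-fold lower (981 ± 32.7 against 801 ± 22.1 FPKM). Il22 was 1.53-fold higher, at 6.98 ± 1.10 against 10.7 ± 0.190 FPKM. Their limma adjusted p-values were 4.39e-07 for Il10, 6.65e-05 for Ifng, 1.44e-04 for Il17a, 0.00208 for Il17f and 0.0102 for Il22. Il10 lies on chromosome 1 (131019845 to 131024974), Il17a on chromosome 1 (20730905 to 20734496) and Ifng on chromosome 10 (118441046 to 118445892). Csf2 (0.931 ± 0.598 against 1.17 ± 0.271 FPKM) and Il13 (0.898 ± 0.476 against 1.20 ± 0.251 FPKM) did not pass the test. Il4 had a mean of 0.445 ± 0.401 against 1.39 ± 0.986 FPKM and was below the level tested, as were Eomes (0.968 ± 0.233 against 0.978 ± 0.175 FPKM) and Zbtb16 (0.90 ± 0.0801 against 0.770 ± 0.177 FPKM).

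**Figure D1:**
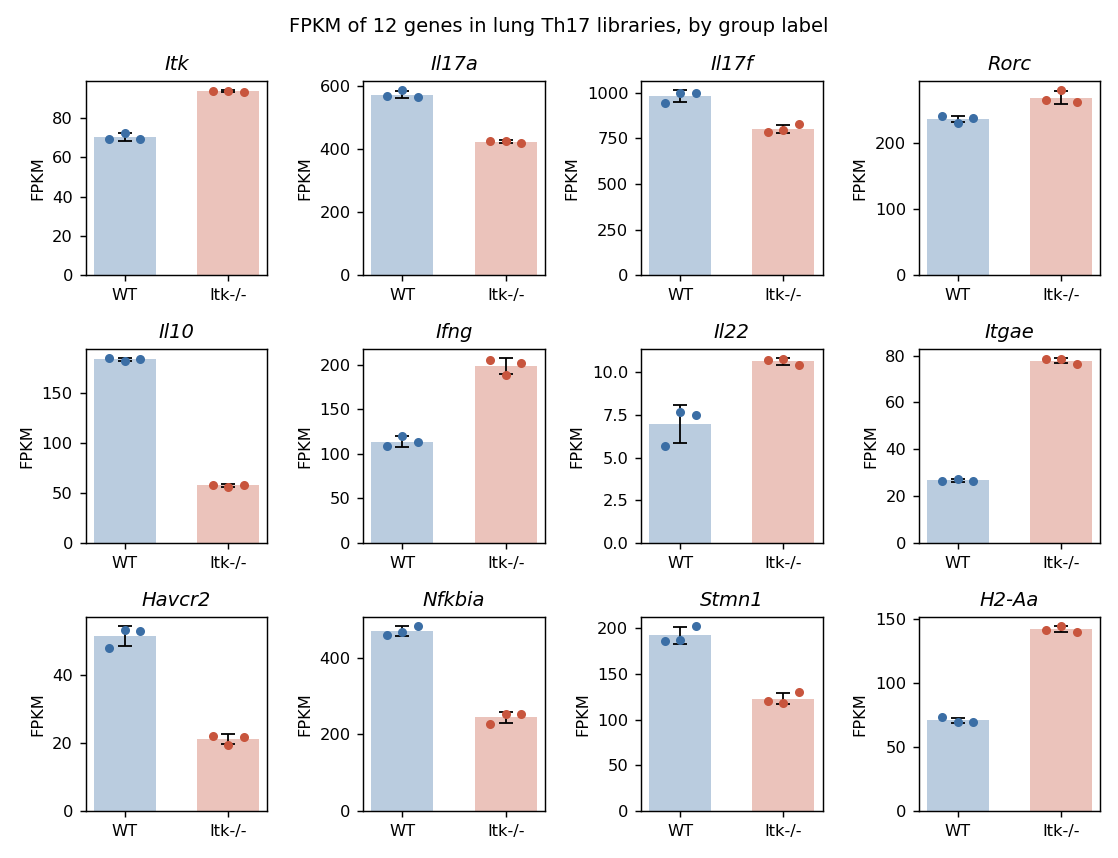
FPKM of 12 genes (vertical axes, from 0) in the libraries labelled WT (blue) and Itk-/- (red). Points are libraries, bars are means and error bars are SD (n = 3). Il10 fell from 184 to 57.9 FPKM and Ifng rose from 114 to 198, while Itk stood at 70.4 and 93.7 FPKM.

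Transcription factors and receptors of these lineages also moved in different directions. Rorc, which encodes the lineage factor RORγt, was 1.14-fold higher (237 ± 5.02 against 270 ± 9.71 FPKM, adjusted p = 0.0172). Tbx21, which encodes the Th1 factor T-bet, was 1.31-fold higher (9.26 ± 0.594 against 12.1 ± 1.01 FPKM, adjusted p = 0.0244). Il23r was 1.42-fold lower (11.8 ± 0.819 against 8.35 ± 1.06 FPKM, adjusted p = 0.0152). Foxp3, whose reporter was used to exclude cells, was at 2.36 ± 0.247 against 1.49 ± 0.142 FPKM (adjusted p = 0.0493). Rora (35.3 ± 2.65 against 39.7 ± 1.81 FPKM), Ccr6 (109 ± 4.75 against 106 ± 2.14 FPKM), Gata3 (24.8 ± 0.451 against 25.3 ± 2.47 FPKM) and Irf4 (43.7 ± 1.04 against 40.1 ± 0.625 FPKM) did not pass the test. Without 1 library, Rorc missed the threshold at an adjusted p of 0.0542 (WT replicate 2) and 0.0589 (Itk-/- replicate 2), in a range over all alternatives of 0.00278 to 0.0671. Il23r missed it without WT replicate 2 (0.0506), Itk-/- replicate 1 (0.0521) or Itk-/- replicate 2 (0.0519), in a range of 0.00813 to 0.0521. Tbx21 missed it without WT replicate 1 (0.0776), WT replicate 3 (0.0737), Itk-/- replicate 1 (0.0808) or Itk-/- replicate 2 (0.0821), in a range of 0.0159 to 0.0821. Foxp3 missed it without any 1 of the 6 libraries, with adjusted p between 0.0666 (without WT replicate 3) and 0.126 (without WT replicate 2), in a range from 0.0163.

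Across the transcriptome, 1696 of 10997 genes tested (15.4%) changed, 809 higher and 887 lower in the libraries labelled Itk-/-. The larger rises included Itgae, the integrin chain CD103 that binds E-cadherin, at 26.7 ± 0.505 against 77.8 ± 1.14 FPKM (2.91-fold, adjusted p = 1.39e-06). Trat1, a TCR-associated adaptor, was at 7.80 ± 2.73 against 27.3 ± 2.38 FPKM (3.50-fold). Il4i1, a secreted amino acid oxidase, was at 1.12 ± 0.993 against 6.50 ± 1.39 FPKM. St6galnac2, Ly6g5b, Ggh, Dtx4, Gpr97, Hid1 and Qpct were 2.67-fold to 3.57-fold higher. Eif3j2 was near 0 in WT (0.00151 ± 0.000502 FPKM) and at 3.99 ± 2.08 FPKM in Itk-/-, but it has a near-identical paralog, Eif3j1, so its value is uncertain.

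The larger falls included Il10, Hey1, a Notch target (13.5 ± 1.57 against 4.403 ± 0.0908 FPKM, 3.06-fold), and Havcr2, the inhibitory receptor TIM-3 (51.4 ± 2.99 against 21.1 ± 1.52 FPKM, 2.44-fold). The 45S ribosomal precursor Rn45s fell 2.71-fold (1147 ± 136 against 423 ± 33.0 FPKM), and Lars2 fell 3.03-fold (266 ± 31.0 against 87.7 ± 10 FPKM). The RNase P and RNase MRP RNAs fell too, Rpph1 2.75-fold and Rmrp 3.07-fold. Rn45s is multi-copy, and Rn45s, Rpph1 and Rmrp lack a poly(A) tail, so their values are uncertain in libraries of polyadenylated RNA. Lars2 ordered the replicates of each group as Rn45s did. Over replicates 1 to 3, Lars2 was at 299, 237 and 263 FPKM in WT and 96.7, 76.9 and 89.5 in Itk-/-. Rn45s was at 1290, 1019 and 1131 FPKM in WT and 447, 386 and 437 in Itk-/-. The Lars2 value may thus be uncertain too, and why it followed Rn45s was not tested. Serp2 was at 4.39 ± 1.21 against 1.40 ± 0.798 FPKM. Scarna6 was at 10.6, 10.2 and 0.864 FPKM in the WT libraries and listed at 0 in the Itk-/- libraries. Pet117 was at 5.58 ± 3.55 against 0.733 ± 0.817 FPKM, and the multi-copy histone genes Hist2h4 and Hist1h4f at 7.30 ± 3.75 against 2.15 ± 0.881 and 2.52 ± 0.887 against 0.567 ± 0.579 FPKM. These last 4 genes missed the threshold in some alternatives, with adjusted p of up to 0.117, 0.116, 0.0735 and 0.101, and Rmrp missed it with robust eBayes (0.059, in a range from 3.98e-04).

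All 1696 changed genes had groups that did not overlap, as had 3973 of all tested genes, where chance gives 10%. A fold of at least 1.5 was reached by 233 higher and 250 lower genes. TPM scaling moved the split to 1231 higher and 654 lower (65.3% higher, against 47.7% as deposited). With 1 library left out the count fell to 1115 (WT replicate 3), 1114 (Itk-/- replicate 1) or 1073 (Itk-/- replicate 2). The count of higher genes fell by over 1.5 times without WT replicate 1 (521), WT replicate 3 (533), or Itk-/- replicate 1 (509), 2 (479) or 3 (527), and the count of lower genes without WT replicate 3 (582). The libraries differed by 0.425 log2 (root mean square over genes) between groups and 0.364 within groups, a difference of 0.0612. Of the 10 splits into 3 and 3, the real one gave the largest such difference, an exact share of 0.1, the smallest possible.

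**Figure D2:**
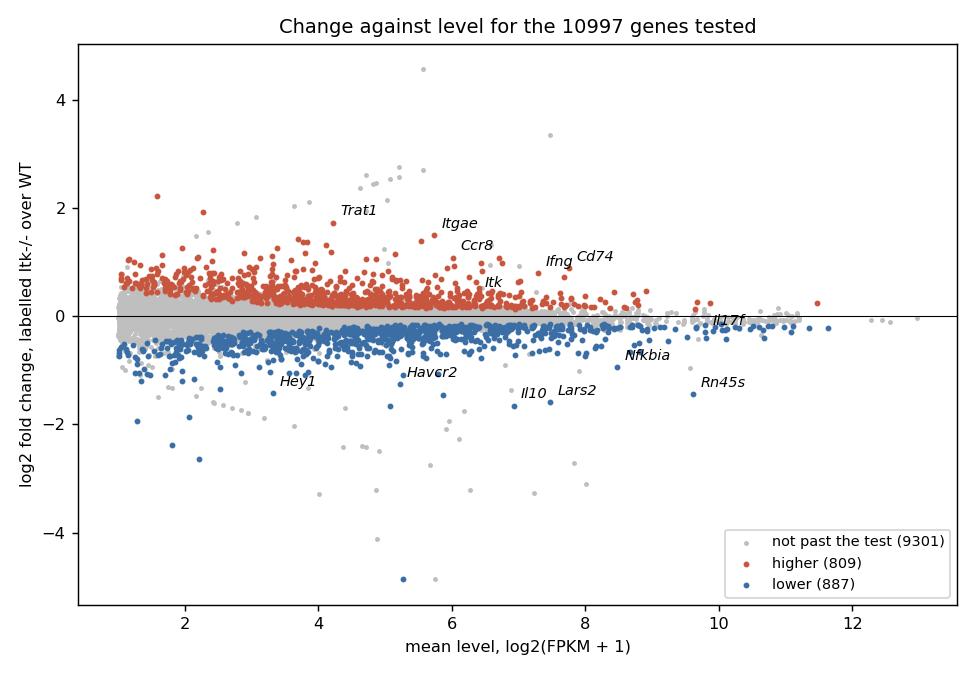
Log2 change (labelled Itk-/- over WT, vertical axis) against mean level in log2(FPKM + 1) (horizontal axis) for the 10997 tested genes. Red points are the 809 higher genes, blue points the 887 lower genes and grey points the genes that did not pass; Il10, Rn45s and Lars2 are among the lower genes and Itgae and Trat1 among the higher.

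Cell cycle genes were lower as a group, with 0 of 38 measured members higher and 33 lower in the libraries labelled Itk-/-. The camera adjusted p was 5.79e-24 at the preset correlation, and the call was lost at an adjusted p = 0.0621 with an estimated correlation. Stmn1, a microtubule regulator, was at 192 ± 9.11 against 123 ± 6.18 FPKM, and Ube2c, a mitotic ubiquitin-conjugating enzyme, at 57.3 ± 3.06 against 35.3 ± 2.88 FPKM. Aurkb and Hmgb2 fell by 0.62 and by 0.37 log2. TCR-induced immediate response genes had 15 members lower, 4 higher and 10 that did not pass. Its camera adjusted p was 2.71e-07, and the adjusted p = 0.0843 with an estimated correlation. Nfkbia, an inhibitor of NF-κB, was 1.92-fold lower (469 ± 12.7 against 244 ± 14.8 FPKM), and Dusp1, Bhlhe40, Tnfaip3 and Nr4a1 were 1.51-fold, 1.44-fold, 1.37-fold and 1.32-fold lower. Egr2 was at 11.3 ± 0.0748 against 13.2 ± 0.548 FPKM, and its adjusted p of 0.0479 rose above the threshold without any 1 of the libraries (0.071 without Itk-/- replicate 2 to 0.133 without Itk-/- replicate 1; 0.0235 to 0.133 over all alternatives). The other higher members were Tnf (56.8 ± 4.08 against 94.3 ± 3.87 FPKM), Tnfsf14 (8.10 ± 1.12 against 15.3 ± 0.289 FPKM) and Cd40lg (88.8 ± 5.26 against 119 ± 5.96 FPKM). Their limma adjusted p-values were 2.27e-04, 7.37e-04 and 0.00201. In the libraries labelled Itk-/- Xist was also 1.53-fold higher and the Y-linked Eif2s3y 1.57-fold lower. The class II gene H2-Aa was 2.01-fold higher and Rn45s 2.71-fold lower there. Of 19 measured heat shock and dissociation stress genes, 10 were lower and 1 higher in the same libraries. Whether the lower TCR-induced genes reflect TCR signalling or tissue handling was not tested. There were 37 cell cycle and 19 TCR-induced members lower when adjusted over the list alone.

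Regulatory T cell markers, follicular helper T cell markers, inhibitory receptors and the non-pathogenic Th17 signature were lower with camera's preset correlation (adjusted p = 5.69e-07, 3.86e-09, 5.19e-05 and 1.73e-04). These calls were lost with an estimated correlation (adjusted p = 0.181, 0.0621, 0.149 and 0.0849). In the same libraries Xist was 1.53-fold and the class II gene H2-Aa 2.01-fold higher. Of 13 regulatory T cell markers, 9 fell and 1, Itgae, rose. Nt5e, the ectoenzyme CD73, was 1.53-fold lower (211 ± 2.45 against 138 ± 2.70 FPKM) and Ctla4 1.34-fold lower (1260 ± 21.9 against 944 ± 2.38 FPKM). Of 11 follicular helper markers, 9 fell and 0 rose, among them Slamf6 (42.1 ± 0.887 against 22.3 ± 1.61 FPKM), Cxcr5, Sh2d1a and Tcf7. Of 12 inhibitory receptors, 7 fell and 0 rose, with Lag3 at 233 ± 3.34 against 146 ± 5.89 FPKM and Btla at 22.4 ± 1.38 against 15.8 ± 0.248 FPKM. The non-pathogenic Th17 signature had 3 of 5 measured members lower (Il10, Ahr and Il6st) and 0 higher. The lower members numbered 9, 11, 8 and 4 when adjusted over the list alone. Il10, Ctla4, Btla, Tigit, Cd200, Pdcd1 and Entpd1 each stand in more than 1 of these lists, so the list calls are not separate results. Havcr2, also among the inhibitory receptors that fell, is a neighbour of Itk on chromosome 11.

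The lists for oxidative phosphorylation, cholesterol synthesis and heat shock with dissociation stress were lower with camera's preset correlation (adjusted p = 2.71e-07, 0.00105 and 7.18e-05), but most members of the first 2 did not pass. These calls were lost with an estimated correlation (adjusted p = 0.149, 0.0843 and 0.0723). Xist was 1.53-fold and H2-Aa 2.01-fold higher, and Rn45s 2.71-fold lower, in these libraries. Oxidative phosphorylation had 7 of 46 members lower and 0 higher, with Uqcrq at 179 ± 4.89 against 143 ± 4.49 FPKM. Cholesterol synthesis had 5 of 23 lower and 0 higher, among them Insig1 (37.4 ± 1.92 against 25.4 ± 1.60 FPKM), Cyp51 and Fdps. Heat shock and dissociation stress genes, some of which respond to tissue handling, had 10 of 19 lower and 1 higher, with Gadd45b at 249 ± 18.8 against 174 ± 8.98 FPKM and Hspa5 at 370 ± 5.87 against 315 ± 3.99 FPKM. Adjusted over the list alone, the lower members numbered 9, 5 and 11.

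The interferon response, the Th1 programme and macrophage and dendritic cell markers were higher with camera's preset correlation (adjusted p = 2.05e-05, 0.0328 and 9.58e-08). These calls were lost with an estimated correlation (adjusted p = 0.129, 0.149 and 0.0621). Interferon-response genes had 9 of 25 members higher and 1 lower, with Igtp, an interferon-inducible GTPase, at 38.8 ± 2.60 against 66.3 ± 2.12 FPKM, Ly6a at 99.9 ± 3.65 against 157.0 ± 1.13 FPKM, and Gbp4 and Stat1 1.45-fold and 1.40-fold higher. The Th1 programme had 6 of 17 higher, among them Ifng, Stat1, Runx3 (39.8 ± 1.05 against 56.3 ± 1.07 FPKM) and Il18r1, and 2 lower, 1 of them Txk. Macrophage and dendritic cell markers, which a sort for CD4+ T cells should exclude, had 11 of 21 higher and 0 lower. The MHC class II gene H2-Aa was at 70.8 ± 2.03 against 142 ± 2.43 FPKM, H2-Eb1 at 44.0 ± 2.31 against 85.0 ± 3.74 FPKM and the invariant chain Cd74 at 150 ± 2.68 against 281 ± 16.3 FPKM. The higher members numbered 10, 8 and 11 when adjusted over the list alone. The Th1 call also ended under TPM scaling (adjusted p = 0.0511; 4.67e-04 to 0.149 over all alternatives).

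**Figure D3:**
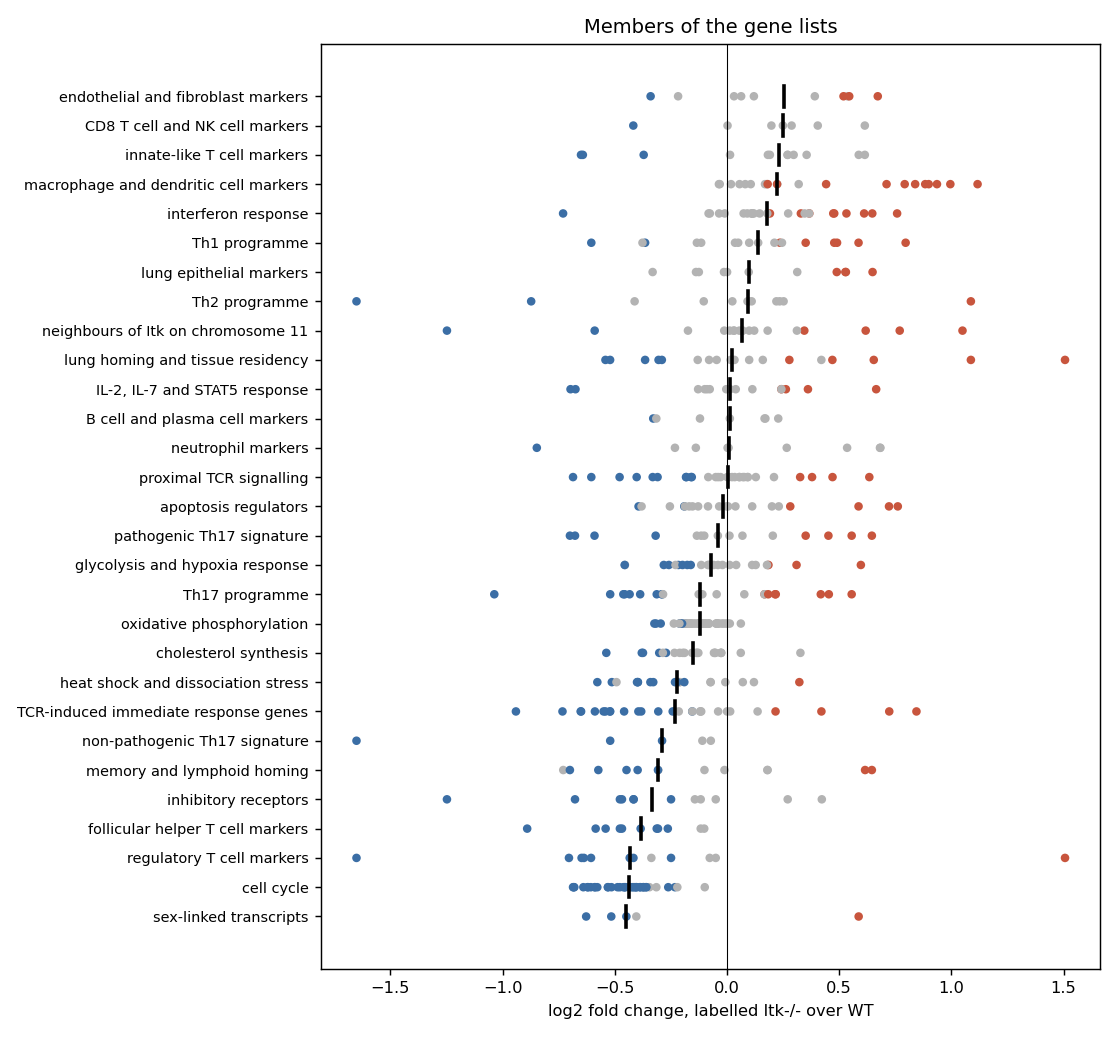
Log2 change (horizontal axis) of the measured members of the 29 tested lists, ordered by their median (black bar). Points are genes, red where higher, blue where lower and grey where the test was not passed; 33 of 38 cell cycle members lie on the lower side in blue.

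Several T cell lists held members that moved both ways. The Th17 programme had 7 of 23 members higher and 9 lower (camera adjusted p = 0.236). Tmem176a and Tmem176b were higher (290 ± 6.58 against 397 ± 10.8 and 360 ± 13.2 against 482 ± 22.2 FPKM), and Il17a, Il17f and Hif1a were lower. The pathogenic Th17 signature had 4 of 15 higher, among them Il7r (63.4 ± 1.66 against 99.8 ± 4.11 FPKM) and Il22, and 4 lower, among them Lag3, Cxcl3 and Lrmp (adjusted p = 0.601). Proximal TCR signalling had 4 of 30 higher and 10 lower (adjusted p = 0.441). In it Cd247, the CD3ζ chain, was at 318 ± 1.34 against 197 ± 1.32 FPKM and Malt1 at 54.0 ± 2.24 against 38.5 ± 0.876 FPKM, while Ubash3a was at 38.1 ± 1.46 against 59.6 ± 1.54 FPKM and Grap2 was 1.39-fold higher. Lung homing and tissue residency had 5 of 19 higher, with Itgae and Cxcr6 (402 ± 11.9 against 557 ± 22.8 FPKM), and 5 lower, with Cd69 (357 ± 12.6 against 245 ± 9.51 FPKM) and Rgs2 (adjusted p = 0.775). Memory and lymphoid homing had 2 of 13 higher and 5 lower, among them S1pr1, Lef1 and Tcf7 (adjusted p = 0.127). The IL-2, IL-7 and STAT5 response had 4 of 15 higher, with Lta and Ccnd2, and 2 lower, Pim1 and Socs3 (adjusted p = 0.601). Adjusted over the list alone, the counts higher and lower were 8 and 11, 4 and 5, 4 and 10, 6 and 5, 3 and 7, and 4 and 2, in the order of these lists.

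The Th2 programme had 1 of 12 members higher, Ccr8 (40.6 ± 5.89 against 87.1 ± 8.26 FPKM), and 2 lower, Il10 and Areg (adjusted p = 0.982). Innate-like T cell markers had 0 of 12 higher and 3 lower, with Blk at 20.8 ± 0.928 against 12.97 ± 1.72 FPKM (adjusted p = 0.685). Glycolysis and hypoxia genes had 3 of 24 higher, with Pfkl at 12.9 ± 0.519 against 20.1 ± 1.52 FPKM, and 7 lower, with Hif1a, Gapdh and Ldha (adjusted p = 0.127). Apoptosis regulators had 4 of 20 higher, with Tnfsf10 and Bcl2l11, which were 1.79-fold and 1.73-fold higher, and 2 lower, 1 of them Casp3 (adjusted p = 0.977). Adjusted over the list alone, the counts higher and lower were 1 and 3, 3 and 3, 3 and 9, and 5 and 6. The median and mean log2 change had opposite signs for the Th2 programme (0.09 and -0.08), proximal TCR signalling (0.0044 and -0.035), B and plasma cell markers (0.013 and -0.026) and apoptosis regulators (-0.018 and 0.048), and the camera test gave the lower direction for each of them. Mitochondrially encoded transcripts had 0 rows in the table and erythroid transcripts had 0 measured members.

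Of the 6 tested lists for other lung cells and sex-linked transcripts that follow, 0 passed camera's test after adjustment, while single members of each did in limma's gene test. Endothelial and fibroblast markers had an unadjusted camera p of 0.0449, and fry called them (adjusted p = 0.00292) and lung epithelial markers (adjusted p = 0.0291). Lung epithelial markers had 4 of 11 higher and 0 lower, with the club cell secretory gene Scgb1a1 at 68.8 ± 2.47 against 99.7 ± 6.24 FPKM (camera adjusted p = 0.162). Endothelial and fibroblast markers had 3 of 10 higher, among them Col3a1 (2.13 ± 0.190 against 3.48 ± 0.142 FPKM), and 1 lower, Pecam1 (adjusted p = 0.1). Neutrophil markers had 0 of 9 higher and 1 lower, Mmp9 (27.9 ± 1.07 against 15.1 ± 1.67 FPKM, list adjusted p = 0.94). B and plasma cell markers had 0 of 7 higher and 1 lower (adjusted p = 0.639), and CD8 T and NK cell markers 0 of 7 higher and 1 lower (adjusted p = 0.465). Of the mast cell, basophil and eosinophil markers only Kit was measured, and it was 1.43-fold lower. Among 5 sex-linked transcripts 1 rose and 3 fell (list adjusted p = 0.127). Xist, transcribed from the inactive X, was at 20.9 ± 0.199 against 31.8 ± 1.66 FPKM, and the Y-linked Eif2s3y and Ddx3y at 33.8 ± 2.48 against 21.6 ± 2.26 and 15.9 ± 0.631 against 10.8 ± 1.36 FPKM. Adjusted over the list alone, the counts higher and lower were 4 and 2 for epithelial, 5 and 1 for endothelial and fibroblast, 0 and 1 for each of the neutrophil, B cell and CD8 lists, and 1 and 4 for sex-linked transcripts.

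Some genes beside Itk on chromosome 11 differed between the groups and others did not pass the test. The fixed list of neighbours had 4 of 18 members higher, 2 lower and 12 that did not pass, and 5 higher and 3 lower when adjusted over the list alone (camera adjusted p = 0.157). Med7 (46436925 to 46442721) was at 17.7 ± 0.916 against 11.4 ± 1.27 FPKM, and Havcr2 (46454935 to 46481255) was 2.44-fold lower. Adra1b was at 2.85 ± 0.406 against 5.54 ± 0.415 FPKM and Pwwp2a 1.29-fold higher. Fam71b (46396559 to 46407982), Gm12169 (46524212 to 46538156) and Gm12171 (46544209 to 46557067) were picked outside the naming rule. Fam71b, between Itk and Med7, was higher, at 0.434 ± 0.160 against 1.97 ± 0.380 FPKM (adjusted p = 0.00448). Gm12169 was at 3.37, 2.997 and 2.17 FPKM and Gm12171 at 4.45, 8.83 and 1.59 FPKM in the WT libraries, and both were listed at 0 in the Itk-/- libraries. On the other side of Itk, the 6 tested genes within 0.5 Mb (Cyfip2, Fndc9, Adam19, Thg1l, Lsm11 and Clint1) did not pass, with adjusted p between 0.0889 and 0.96.

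**Figure D4:**
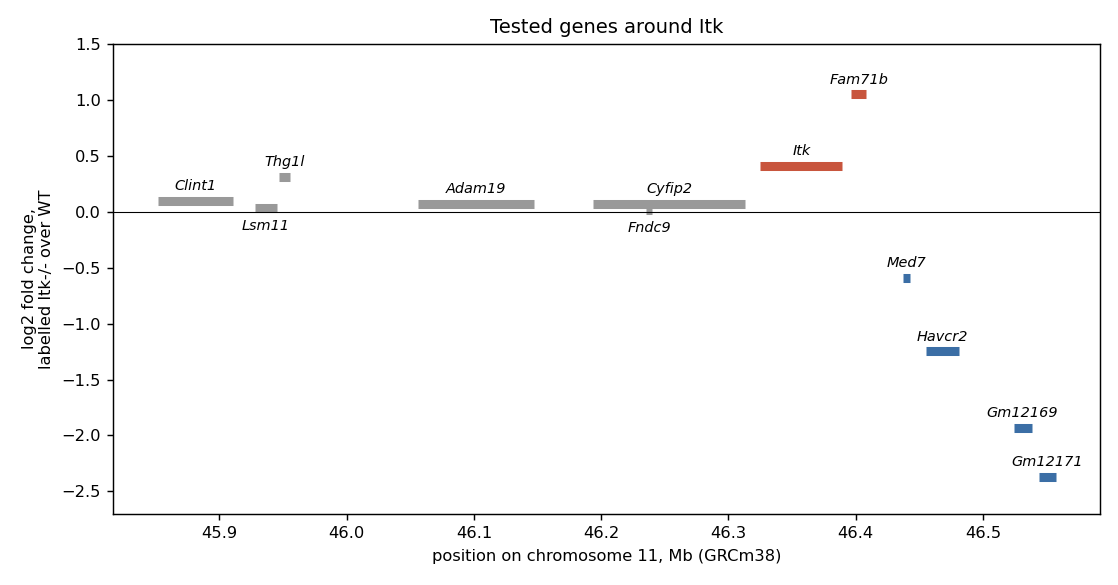
Log2 change (labelled Itk-/- over WT, vertical axis) of tested genes along chromosome 11 around Itk (horizontal axis, Mb on GRCm38). Bars span the genes, red where higher, blue where lower and grey where the test was not passed. On the same side of Itk, Fam71b was higher and Med7, Havcr2, Gm12169 and Gm12171 were lower. The 6 tested genes within 0.5 Mb on the other side did not pass.

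In all, 12 of 29 lists passed with camera's preset correlation, 3 higher and 9 lower, and fry called 20. With an estimated correlation 0 passed, the smallest adjusted p was 0.0621, and 8 had an unadjusted p under 0.05. Camera with the preset correlation also called up to 7 lists in the other splits of the 6 libraries.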

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

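The minimum fold of 1.5 and the fit without small RNA rows were chosen after seeing the data. Of 125 called genes chosen by the naming rule other than Itk, 21 lost the call in at least 1 of up to 18 settings, and 0 changed sign. The count of changed genes stayed within 1.5 times of 1696 under each change of pseudocount, filter, scaling and eBayes form, but TPM scaling raised the higher genes to 1231. A minimum fold of 1.5 left 483 genes (233 higher, 250 lower), by its construction. With 1 library left out, changed genes ranged from 1073 to 1298, higher from 479 to 613 and lower from 582 to 688, with fewer libraries in the fit. Replicate numbers gave no sign of pairing. The correlations of deviations were -0.047, -0.062 and 0.011, and no WT library correlated best with the Itk-/- library of its own number. The replicate block gave 1304 changed genes (575 higher, 729 lower). Itk stayed higher without each library, by 0.40 to 0.43 log2. For the gene lists, an estimated correlation left 0 calls (8 at an unadjusted p under 0.05) and fry, which tests another question, called 20.

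None of the values below that turned sign had passed its test, and the cause was not tested. For genes the log2 change was 0.0078 for Ccr6 and 0.014 for Tec under TPM scaling, and -0.037 to 0.099 for Gata3 with 1 library left out. For lists the adjusted p is given here with the sign of its direction. The Th2 programme gave 0.684 with no filter, 0.996 with median-ratio scaling, 0.965 with the replicate block and -0.986 to 0.977 with 1 library left out. Apoptosis regulators gave 0.930 with TPM scaling, 0.926 with quantile normalization, 0.118 with fry and -0.977 to 0.937 with 1 library left out. Neutrophil markers gave -0.786 with TPM scaling, -0.982 with quantile normalization and -0.270 with fry. With a minimum mean FPKM of 5, innate-like T cell markers gave -0.617 and lung homing and tissue residency -0.768. Innate-like markers gave -0.679 with fry, and proximal TCR signalling gave 0.660 with quantile normalization. The estimated depth differed by a factor of 1.45 at most, which limits genes near 1 FPKM, the lowest mean tested.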

Other observations

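All tests in this part were chosen after the results they concern had been seen, except the test of dendritic cell genes and the splits for the gene lists, and the genes below were picked after their values were seen. On chromosome 6, the adjacent IL-17 receptor chains Il17rc (16.2 ± 2.34 against 34.5 ± 2.23 FPKM) and Il17re (41.6 ± 3.38 against 77.8 ± 2.53 FPKM) were higher in the libraries labelled Itk-/- (means of the WT libraries are given first). Of 29 histone genes tested, 4 were lower and 1 higher, where 15.4% of all tested genes were called.

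The Itk level leaves open what the genotype labels stand for. An exchange of the 2 groups' labels, with an allele that removes the transcript, would put Itk near 0 in the libraries labelled WT, but the lowest of them stood at 73.8% of the Itk-/- mean. Within 5 Mb of Itk 15 of 43 genes were called, an odds ratio of 2.962 against genes elsewhere (95% interval 1.47 to 5.75, Fisher's exact p = 0.00202). Their share was above that of 99.4% of 10092 windows centred on other genes. Windows centred on the neighbours of Itk were among these and overlap its own window. The rank is therefore not a comparison with the rest of the genome alone. The excess of called genes does not settle whether the groups carry the same chromosome there, since neighbours can change together with the cell state. The 15 include the interferon-inducible Irgm1 and Tgtp2. A strain difference carried with the allele and an effect of the allele on nearby genes were not tested. A transcript of the disrupted allele that is still counted in the gene-level FPKM, at a ratio of 1.332, may explain the level, and it stays open because no exon-level value was analysed here.

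The groups may also differ in their mix of male and female mice, since Xist was higher and Y-linked transcripts were lower in the libraries labelled Itk-/-. A mix of sexes can move a gene by no more than Xist (up to 1.62-fold between 2 libraries) or the Y-linked genes (down to 0.395-fold). It cannot alone account for 76 called genes that lay beyond that bound in all library pairs, 69 higher and 7 lower, among them Il10, Itgae, Trat1, Ccr8 and H2-Aa. For 1616 other called genes, Ifng and Il17a among them and the sex-linked ones left out, sex and genotype cannot be told apart, as no library came from 1 sex alone. Xist varied by 0.953% (coefficient of variation) among the WT and 5.22% among the Itk-/- libraries.

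The MHC class II transcripts H2-Aa, H2-Ab1, H2-Eb1 and Cd74 had a median rise of 0.926 log2, computed here with a pseudocount of 0.1. Carried-over macrophages as the whole source would raise their own transcripts alike, but 12 macrophage genes had a median of 0.1586 (bootstrap 95% interval 0.0383 to 0.280), above 98.7% of random lists but short of the class II rise, with 4 higher and 0 lower, and Lyz2 was at 263 ± 3.27 against 298 ± 12.6 FPKM and Apoe at 55.5 ± 3.90 against 56.2 ± 4.73 FPKM. A lower share of T cells with all other cells alike would raise macrophage genes as much, but the 8 with a mean of at least 10 FPKM had a median of 0.144 and a highest value of 0.467, below the lowest class II gene at 0.848. Carried-over dendritic cells stay a candidate source, since 9 of 15 further dendritic cell genes rose and their median of 0.6488 lay above all of 10000 random lists matched on level. Flt3 was at 1.66 ± 0.160 against 3.60 ± 0.183 FPKM and Cst3 at 223 ± 8.18 against 288 ± 6.49 FPKM, although H2-DMa was at 28.3 ± 2.53 against 29.1 ± 2.69 FPKM. The sort for TCRβ and CD4 should exclude such cells. Transcripts of other lung cells were nonetheless present in both groups, such as Lyz2 (values above) and the club cell gene Scgb1a1 (68.8 ± 2.47 against 99.7 ± 6.24 FPKM). The dendritic cell list includes the class II pathway genes Ciita, H2-DMa, H2-DMb1 and H2-DMb2, which may move with class II in any cell. Of these, Ciita (1.90 ± 0.164 against 3.24 ± 0.286 FPKM) and H2-DMb1 (4.74 ± 0.129 against 7.57 ± 0.860 FPKM) were among those that rose. The list is therefore not fully separate from the class II rise. Class II expression by the T cells themselves, as an effect of genotype, was not tested.

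The 10 splits of the 6 libraries into 3 and 3 are too few for a share under 0.05. The real split gave 1696 changed genes against 2 at most in the others, 809 higher against 1, 887 lower against 1 and 12 gene lists against 7, and 1 split of the 10, the real one, gave each value.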
